A study of Homo sapiens with 12 samples.

How the data were processed

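Gene expression was measured in Daudi cells, a B cell line from a Burkitt lymphoma, on 12 arrays of 1 colour. Per the labels, total RNA was turned into biotinylated cRNA for CodeLink expression arrays, and each array carries 1 sample. The titles put 3 arrays in each of 4 groups: control, an antibody against CD40, IL-4, and both stimuli together. They do not give the doses, 1 ug/mL of antibody and 10 ng/mL of IL-4, nor call the antibody agonistic or the control untreated. They give 6 hr for the 3 treated groups and no time for the control. The titles number the arrays of each group 1 to 3. No label says that the arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

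The deposited values are spot intensity values on a linear scale, 1 table for the series. From the values themselves, background had been subtracted and each array scaled by the authors: 244 to 1280 values per array lay at or below 0, and the array means lay between 0.994 and 1.01. The software for feature extraction, background correction and scaling is not given in the sources used here. Of 54840 probes, 54234 to 54608 had a value on an array, and 232 to 606 were missing. The array medians lay between 0.110 and 0.164, a range of 0.57 on the log2 scale, which exceeded the limit of 0.1 set for leaving the arrays as they were. Each array was therefore centred after scaling by the authors, so that its median equalled the geometric mean of all array medians. Values were floored at the 10th percentile of all scaled values (0.0240) and log2 was taken. What the scale of the intensities means in RNA amounts stays unknown, and the number of arrays limits the precision.

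Probes were tested if they lay above their array's 40th percentile on at least 3 of the 12 arrays and had at least 2 values in every group, which left 35467 probes. Missing values removed 14 of the probes above that level. Of the tested values, 1130 (0.267%) stood at the floor. Probe names came from the platform's annotation, which gave 1 gene symbol to 23472 probes, several to 905 and none to 30463. Of the probes with 1 symbol, 23434 matched a current RefSeq gene record (GRCh38.p14, used for names alone) and 0 were renamed. Among the tested probes 16953 had 1 symbol, 695 had several and 17819 had none. The named probes covered 13849 genes, and 2640 of these had more than 1 tested probe. A gene was represented by its tested probe with the highest mean level, and no gene was named from a probe with several symbols.

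The choices that follow were fixed before the data were examined, except where said otherwise. A linear model with 4 group means was fitted to all 12 arrays with limma (version 3.58.1 in R 4.3.3), so that the groups shared 1 estimate of the spread (median total degrees of freedom 12.2). Errors given with log2 changes are standard errors from this model. The contrasts were each stimulus and the combination against control, the combination against each single stimulus, the single stimuli against each other, and the interaction, which is the combination minus both single changes on the log2 scale. A probe was called at an adjusted p under 0.05 by the Benjamini-Hochberg method within a contrast. Intensity values on the log2 scale give folds relative to the array medians. Any background left in dim probes makes folds too small, and background subtracted in excess makes them too large. Which of these held for a probe is not known.

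The genes named in the text were chosen by rule. The rule took 26 sentinel genes of CD40 and IL-4 biology, of which 22 were measured by a tested probe of 1 symbol. Of the others, CCL4 had tested probes of several symbols only. The probe shared with CCL4L1 and CCL4L2 rose by 2.59 with anti-CD40 (limma adjusted p = 0.0127) and 3.46 with the combination (0.000906). The probe shared with ALOX5AP was not called (0.02 and -0.15). The rest were not analysed here. It also took the 8 largest rises and falls called against control among genes whose 3 treated arrays lay apart from the 3 control arrays, and the 3 called members with the largest change of each gene list past its threshold against control. For the other contrasts it took the 6 largest called rises and falls and any called sentinel gene. Genes named outside this rule are marked as chosen after their values were seen, and so were the 9 genes and 8 lists drawn in the plots.

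Of gene lists, 33 were tested with camera (preset correlation 0.01, 1 probe per gene, adjusted over the lists). Lists can share members, so lists past the threshold are not separate results. BCL2A1 and CFLAR stand in NF-kB target genes and survival genes. CCL3 stands in NF-kB target genes and chemokines, LTA in NF-kB target genes and cytokines, and CCL17 in chemokines and IL-4 and STAT6 target genes. Beside each list stand its members called over all probes, those called when adjusted over the list alone, and the adjusted p with an estimated correlation. The fry method served as another test. It asks whether the genes of a list move on balance 1 way and does not set them against other genes.

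Whether equal replicate numbers pair the arrays was decided from the deviations of each array from its group mean, before the calls of any fits were compared. All 18 pairs of arrays with the same number in different groups had a correlation above 0.1 (0.234 to 0.713, median 0.490). Pairs with different numbers lay between -0.546 and 0.173 (median -0.328), and for 12 of 12 arrays the closest partner carried its own number. The numbers were taken to pair the arrays on this basis, which comes from the data and not from a label. The model planned for the calls had no block, and the fit with the replicate number as a block is given beside a result where it changes a call or moves a count by over 1.5 times. The estimated correlation of the gene lists and fry used the fit without the block only. Differences between replicate numbers can therefore enter both.

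The fits were tested on 12 simulated arrays of 35467 probes, drawn with the real means, replicate deviations and spread and with 200 probes changed in anti-CD40 against control. The draw holds the replicate structure by construction. Without the block, 11% of changes of 1 on the log2 scale and 72% of changes of 2 were recovered, with 84 probes called, 1 of them unchanged. With the block, 58% and 91% were recovered, with 153 probes called, 4 of them unchanged. In the simulated IL-4 arrays, which held no change, limma called 0 probes in either fit.

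Alternatives were quantile normalization, no centring, another floor or none, another filter or none, the replicate block, a fit on the compared groups only, eBayes with trend and robust moderation, a further requirement of a 2-fold change, 1 probe per gene, each other probe of a named gene, and each array left out in turn. Chosen after seeing the data were the block together with quantile normalization, the block without centring, and the removal of replicate 2 from every group. When 1 array of a group was left out, the remaining arrays were fitted with the shared spread. These fits had no block, so leaving out an array also left the replicate numbers unequal between the groups. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. No column of values was left unused.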

Results

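Daudi cells, a B cell line from a Burkitt lymphoma, were stimulated through CD40, a receptor through which T cells activate B cells, and with IL-4, a cytokine that signals through the receptor chain IL4R and the transcription factor STAT6. The 12 arrays compare untreated cells with cells given an agonistic anti-CD40 antibody, IL-4 or both for 6 hr, with 3 arrays per group. No time is given for the control, so comparisons with control and the interaction may hold a difference in culture time. Between arrays the correlation of log2 values over the tested probes lay between 0.953 and 0.990. All levels are intensities on the authors' scale after the arrays were brought to a common median, and folds carry 95% intervals where given.

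The first question was what CD40 ligation alone did. With anti-CD40, EBI3, a subunit shared by IL-27 and IL-35, rose 36.8-fold (95% interval 24.6 to 55.2, n = 3 arrays per group). CXCL10 and CXCL11, interferon-inducible ligands of CXCR3, rose 29.9-fold and 10.1-fold, and CCL17, a ligand of CCR4, rose by 3.46 ± 0.27 on the log2 scale. The death receptor FAS rose 16.6-fold, the kinesin gene KIF26B 19.8-fold, TRAF1, an adaptor of TNF receptor signalling, 9.60-fold and BCL2A1, an anti-apoptotic BCL2 relative, 8.37-fold. NFKBIA, the inhibitor that NF-kB itself induces, rose 6.85-fold. Several of these folds rest on dim controls. The log2 control means of EBI3, BCL2A1, CXCL11 and KIF26B were -3.21, -3.21, -3.07 and -4.21. They lay below that of CCL17 (-2.67), while those of FAS, TRAF1, CXCL10 and NFKBIA lay above it. Background left in these controls was tested for CCL17 only.

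Smaller rises were called for the caspase-8 inhibitor CFLAR (log2 change 2.49 ± 0.24), the chemokine CCL3 (2.17 ± 0.29), the guanylate-binding GTPase GBP1 (2.16 ± 0.32), the costimulatory ligand CD80 (1.89 ± 0.25), the IL-2 receptor chain IL2RA (1.79 ± 0.27) and lymphotoxin LTA (1.41 ± 0.22). The rises of IL2RA and LTA also rest on dim controls, with log2 control means of -4.49 and -3.74. IER5, an immediate early gene, rose by 1.92 ± 0.28. DDX11-AS1, a non-coding RNA, fell by 1.25 on the log2 scale (SE 0.19, limma adjusted p = 0.0242). In each of these calls the 3 treated arrays lay on 1 side of the 3 control arrays. The naming rule required this of the largest rises and falls, so it adds no support to their calls. The adjusted p from limma was 2.92e-06 for EBI3, 1.2e-05 for CXCL10 and KIF26B, 0.000105 for FAS and CCL17 and 0.000272 for CXCL11. It was 5.35e-05 for TRAF1, 5.5e-05 for NFKBIA and 0.000569 for CFLAR.

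In all, 51 probes were called by limma, 49 higher and 2 lower, among them 35 genes higher, 1 gene lower and 12 probes without a single symbol. An unadjusted p under 0.05 was reached by 1332 probes, against 1773 expected of uniform p-values. The spread of this fit holds the differences between replicate numbers, so the gap does not show fewer changes than chance gives. With the replicate number as a block, 316 probes were called (288 higher, 28 lower), among them all 51, and 3551 had an unadjusted p under 0.05. The block also called CD40 itself (log2 change 1.82, adjusted p from 0.798 to 0.000169) and TNFAIP3, an inhibitor of NF-kB signalling (2.09, from 0.281 to 0.00104). The other sentinel genes were not called in either fit. Their log2 changes were -0.53 for BCL6, -0.41 for IL4R, -0.09 for CCL22, 0.09 for CD86, 0.13 for CISH, 0.12 for TNF, 0.51 for the low-affinity IgE receptor FCER2, 0.52 for ICAM1 and STAT6, 0.58 for BCL2L1 and 0.62 for SOCS1. IRF4 gave 1.53, with 2 of its 3 control arrays at the floor. The CD86 change had a standard error of 0.48 and lay between -0.37 and 0.73 over the alternatives.

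The number of called probes moved with single arrays and with scaling. It was 27 without control replicate 1, 23 without control replicate 3, 28 without anti-CD40 replicate 1 and 30 without anti-CD40 replicate 2, against 113 after quantile normalization, 86 without centring and 33 without a filter. Some of the smaller calls ended when an array was left out. Without the block such a loss may come from the array or from replicate numbers left unequal, which were not told apart. CCL3 reached adjusted p = 0.054 to 0.0633 without control replicate 1 or 3 or anti-CD40 replicate 1 or 3, BCL2A1 0.0624 without control replicate 3, and CD80 0.051 to 0.0564 without control replicate 2 or 3 or anti-CD40 replicate 1. IER5 and IL2RA lost the call whichever of the 6 arrays was left out (0.0564 to 0.133), LTA when any array but control replicate 2 was left out (0.0772 to 0.137), GBP1 when any array but anti-CD40 replicate 2 was left out (0.0654 to 0.107) and DDX11-AS1 when any array but anti-CD40 replicate 3 was left out (0.079 to 0.179). Without a filter GBP1, IER5, IL2RA, LTA and DDX11-AS1 lost it (0.0551 to 0.092), and in the fit on the compared groups only GBP1, LTA and DDX11-AS1 (0.0551 to 0.227). DDX11-AS1 also lost it without centring (0.059). Without replicate 2 of every group, an alternative chosen after the data were seen, the calls of CFLAR (0.0574), LTA (0.174), BCL2A1 (0.179), IL2RA (0.181) and DDX11-AS1 (0.208) ended, and that of IER5 just failed the threshold. Of 2 other CFLAR probes neither was called, and 1 went the other way (-0.36), while the other probes of KIF26B and FAS rose too.

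**Figure D1:**
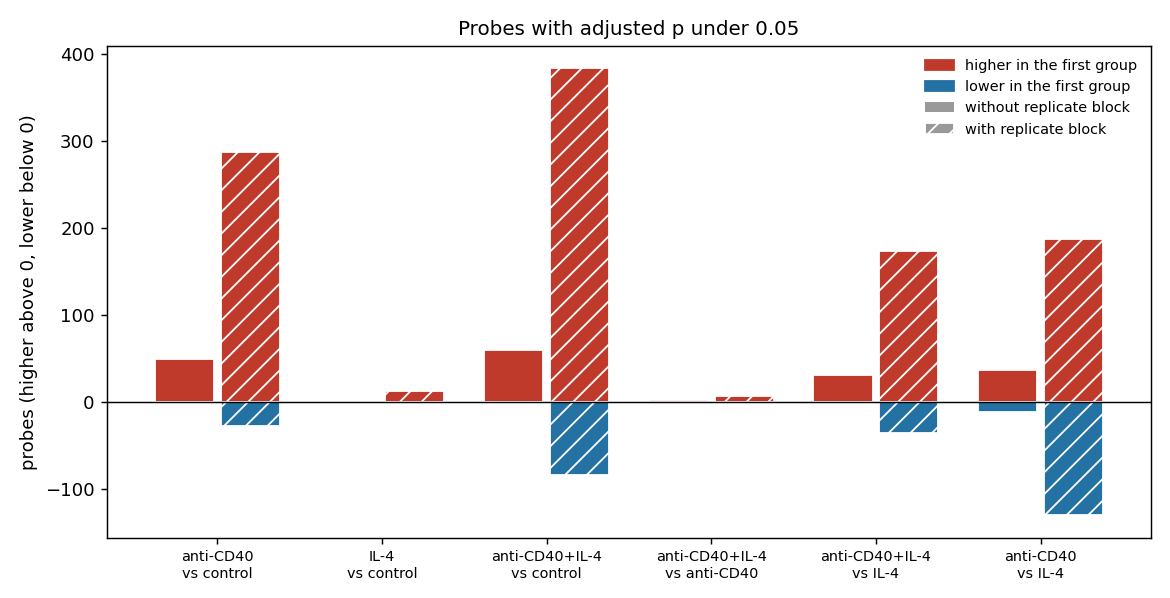
Number of probes called higher (bars above 0) or lower (bars below 0) at an adjusted p under 0.05 in limma in each of the 6 pairwise comparisons, without (plain) and with (hatched) the replicate number as a block. Anti-CD40 against control gave 51 probes without the block and 316 with it, and IL-4 against control 1 and 12.

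**Figure D2:**
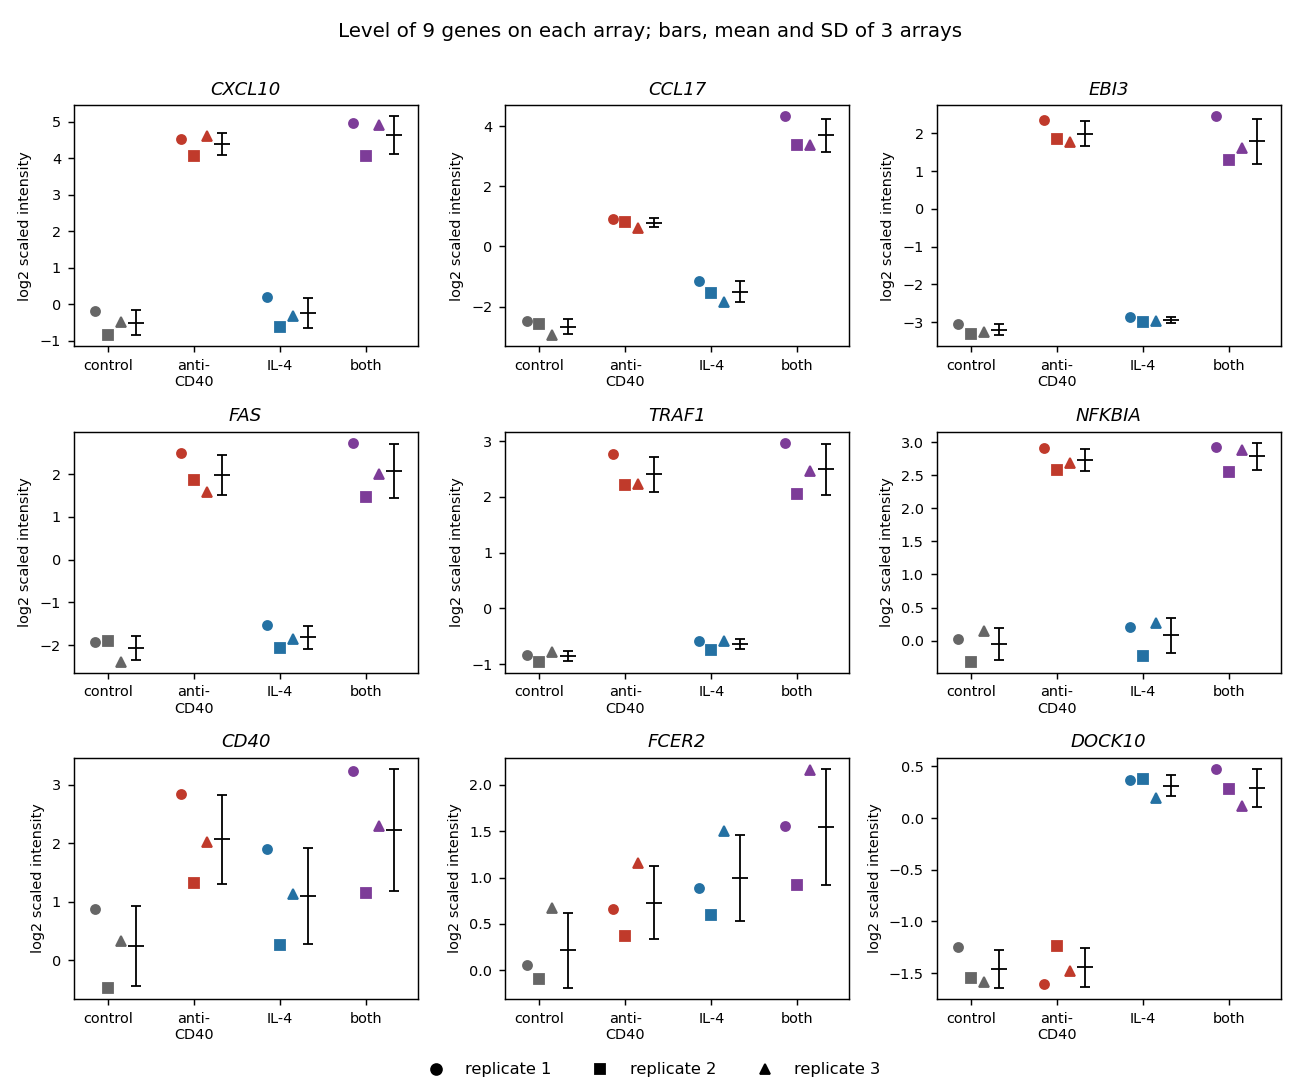
Log2 scaled intensity of 9 genes (vertical axes) on each of the 12 arrays, grouped by treatment, with the marker showing the replicate number, the middle line the group mean and the error bar 1 SD of 3 arrays. CCL17 had a mean scaled intensity of 0.158 in control, 1.73 with anti-CD40, 0.359 with IL-4 and 13.6 with both, and DOCK10 was higher in both groups with IL-4.

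Among gene groups, camera with the preset correlation placed NF-kB target genes higher after anti-CD40 (adjusted p = 7.85e-41), with adjusted p = 0.152 with an estimated correlation. Of 28 measured members, 7 were called higher and 0 lower, 21 were not called, 19 were called higher when adjusted over the list alone, and the median log2 change was 0.97. TRAF1, BCL2A1 and NFKBIA led the called members. The NF-kB subunit genes RELB and NFKB2 had log2 changes of 1.39 each, called over the list alone. Members named here and for the combination that were not called over all probes were chosen after their values were seen. By fry 3 lists passed, NF-kB target genes and the next 2 lists, each with an adjusted p of 0.0171.

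Costimulation and activation surface molecules were shifted up, with FAS, CD80, IL2RA and the adhesion ligand CD58 (1.47 ± 0.19) called among 20 measured members and 9 higher when adjusted over the list alone (camera adjusted p = 6.62e-19, adjusted p = 0.152 with an estimated correlation). Chemokines and receptors held 4 called rises in 14, those of CXCL10, CCL17, CXCL11 and CCL3, and 6 when adjusted over the list alone (camera adjusted p = 1.19e-12, adjusted p = 0.208 with an estimated correlation). The chemokine receptors CXCR4, CXCR5 and CCR7 gave -0.14, 0.20 and -0.06. Of the 20 interferon-stimulated genes measured, GBP1 alone was called over all probes, 8 were higher when adjusted over the list alone and 10 with the replicate block. The antiviral genes RIGI, IFIT1 and MX1 gave 2.05 ± 0.48, 1.51 ± 0.42 and 1.37 ± 0.50 on the log2 scale, and the median of the list was 0.87 (camera adjusted p = 1.38e-13, adjusted p = 0.565 with an estimated correlation).

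Survival genes were shifted up (camera adjusted p = 2.24e-05, adjusted p = 0.591 with an estimated correlation). BCL2A1 and CFLAR, which are also in the list of NF-kB target genes, were the 2 of 10 members called, also 2 over the list alone. Of 15 genes of MAPK and receptor feedback, 0 were called by limma over all probes and 5 were higher when adjusted over the list alone, led by the ERK phosphatase DUSP5 (1.67 ± 0.36). Immediate early genes had IER5 as the 1 called member of 19 and 2 over the list alone. The camera adjusted p of these 2 lists was 6.47e-05 and 0.002, with adjusted p = 0.591 with an estimated correlation for both. Germinal centre B cell genes were the 1 list shifted down. None of the 17 members was called as a fall by limma, 3 of 17 lay above 0, and the median log2 change was -0.26 (camera adjusted p = 0.0066, adjusted p = 0.930 with an estimated correlation). The list's member LMO2, a transcription factor of germinal centre B cells, gave 1.72 ± 0.37 and was the 1 member called over the list alone.

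The remaining 4 lists past the threshold were MHC class II presentation (16 measured, 0 called, 1 over the list alone, HLA-DQA1 with 1.31 ± 0.23), IL-4 and STAT6 target genes (16, 1 called, 2 over the list alone), cytokines (14, with EBI3 and LTA called and 2 over the list alone) and JAK-STAT and SOCS components (20, 0 called and 0 over the list alone). Their camera adjusted p was 0.00282, 0.0066, 0.00723 and 0.0204, and adjusted p = 0.930, 0.930, 0.832 and 0.930 with an estimated correlation. Quantile normalization ended the call of the IL-4 and STAT6 list (0.0926) and began that of CD40 signalling components (0.0339). The replicate block ended the call of cytokines (0.0660) and added CD40 signalling components (0.0487), MHC class I presentation (0.00122), MYC and ribosome biogenesis genes (0.0487) and cholesterol synthesis (0.00131).

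**Figure D3:**
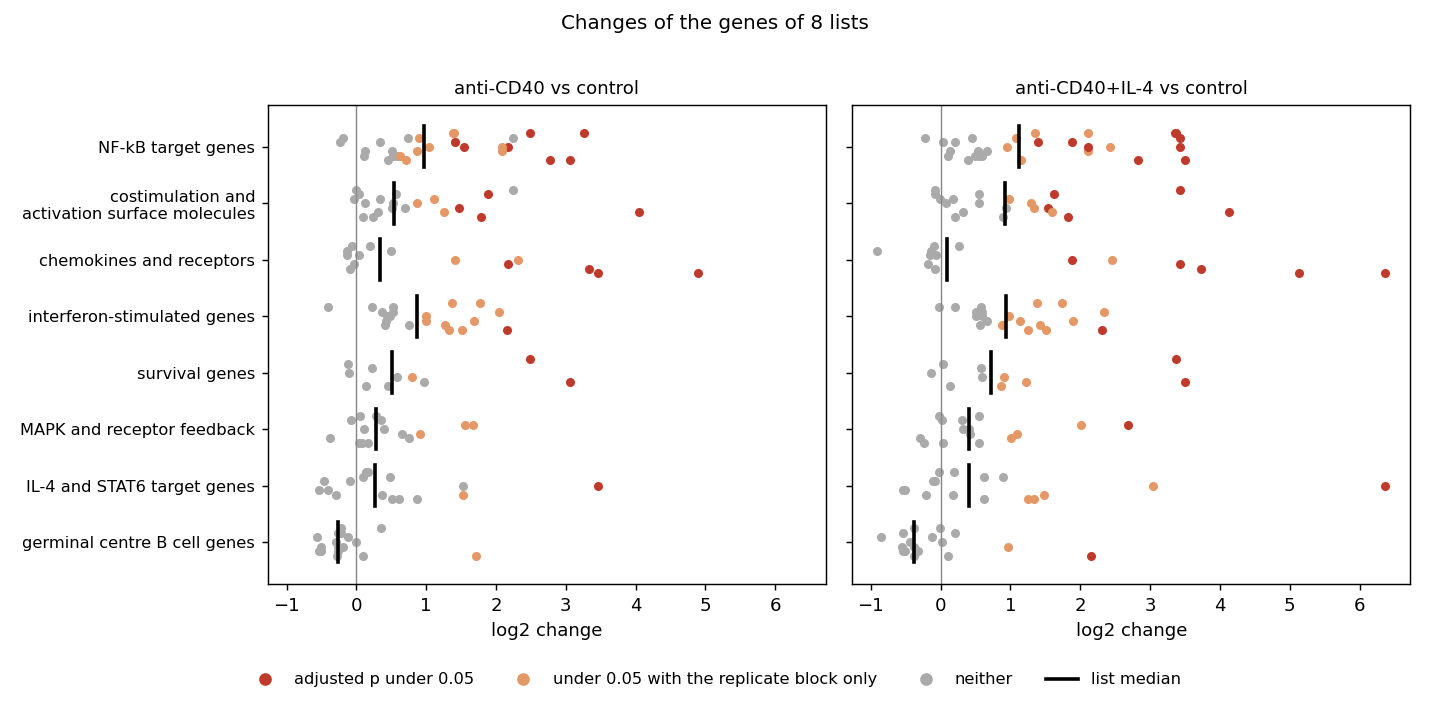
Log2 change of each measured member (points) of 8 gene lists in anti-CD40 against control and in the combination against control, coloured by whether the member was called without the block, with it, or not; the black line is the list's median. NF-kB target genes had medians of 0.97 and 1.12, interferon-stimulated genes 0.87 and 0.93, and germinal centre B cell genes -0.26 and -0.38.

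IL-4 alone changed 1 transcript past the threshold. DOCK10 rose 3.42-fold (95% interval 2.61 to 4.47, n = 3 arrays per group, log2 change 1.77 ± 0.18, limma adjusted p = 0.0115), with all 3 IL-4 arrays above all 3 control arrays, which the naming rule required. CCL17 was 2.24-fold higher (1.48 to 3.39) and FCER2, a classical IL-4 target of B cells, 1.72-fold higher (1.02 to 2.90), but neither was called (adjusted p = 1.00 for both). SOCS1, a feedback inhibitor of cytokine signalling, gave a log2 change of 0.82 ± 0.46, CD40 0.85 ± 0.57, CCL3 0.78 ± 0.29, IRF4 0.49 ± 0.59, ICAM1 0.35 ± 0.31 and BCL6 0.28 ± 0.41. The other 14 measured sentinel genes lay between -0.03 and 0.27.

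An unadjusted p under 0.05 was reached by 785 probes, against 1773 expected of uniform p-values, a gap with the same limit as for anti-CD40. With the replicate block 12 probes were called, all higher, and 2724 had an unadjusted p under 0.05. Beside DOCK10 these were, chosen after their values were seen, both probes of the MAPK-interacting kinase gene MKNK1 (1.74 and 1.12), the natriuretic peptide gene NPPA (1.49), TEX14 (1.36), BLOC1S6 (1.34), the kinase gene MAP3K8 (1.27), ABAT (1.12) and LMO2 (1.09). The other 3 were a probe of several symbols and 2 without a symbol. CCL17 and FCER2 stayed outside the threshold with the block (limma adjusted p = 0.0581 and 0.135). The DOCK10 call ended after quantile normalization (adjusted p = 0.220), without centring (0.0969), in the fit on the compared groups only (0.307) and without control replicate 2 (0.130), control replicate 3 (0.132), IL-4 replicate 2 (0.108) or IL-4 replicate 3 (0.0749). It also ended without replicate 2 of every group (0.303). Without each of these 4 single arrays limma called 0 probes each, with 1104, 496, 779 and 698 at an unadjusted p under 0.05, and without IL-4 replicate 1 it called 3. The other DOCK10 probe gave a log2 change of -0.24.

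No gene list passed the threshold for IL-4 alone, 0 of 33 by camera or fry. IL-4 and STAT6 target genes came closest, with 0 of 16 members called by limma over all probes, 1 member (CCL17) higher over the list alone, a median log2 change of 0.23 and a camera adjusted p = 0.116. With the block 3 lists passed, IL-4 and STAT6 target genes, G2 to M phase genes and interferon-stimulated genes, each at 0.0383, with adjusted p = 0.999 with an estimated correlation and no block. The median over all probes was 0.10 in this comparison and -0.01 without centring, and these medians stand against it. Housekeeping genes had a median of 0.21 here.

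With both stimuli together CCL17 had the largest rise of a named gene, 82.5-fold over control (95% interval 54.6 to 125, n = 3 arrays per group, limma adjusted p = 6.3e-07), from a mean scaled intensity of 0.158 ± 0.0261 (SD) to 13.6 ± 5.56. CXCL10 rose 35.2-fold, EBI3 32.0-fold, KIF26B 18.5-fold, FAS 17.5-fold, CXCL11 13.3-fold, BCL2A1 11.3-fold and CCL3 10.8-fold. The maturation marker CD83 rose 10.7-fold (4.73 to 24.4), CFLAR 10.3-fold, TRAF1 10.2-fold, NFKBIA 7.12-fold and DUSP5 6.41-fold.

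CD80, IL2RA, LTA and IER5 rose by 1.62 ± 0.25, 1.83 ± 0.27, 1.40 ± 0.22 and 1.76 ± 0.28 on the log2 scale, and GBP1 and LMO2 by 2.31 ± 0.32 and 2.15 ± 0.37. DDX11-AS1 fell by 1.36 (SE 0.19, limma adjusted p = 0.0123). The limma adjusted p was 5.28e-06 for CXCL10, 2.94e-06 for EBI3, 6.22e-05 for FAS and CXCL11, 0.000118 for CCL3 and 0.0268 for CD83. In every call named here the 3 arrays of the combination lay on 1 side of the 3 control arrays. The naming rule required this of the largest rises and falls. Of the sentinel genes outside the threshold, BCL6 gave -0.54, IL4R -0.51, CCL22 -0.08, CISH -0.03, TNF 0.13, STAT6 0.38, ICAM1 0.55, BCL2L1 0.59 and CD86 0.90.

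Of 61 called probes 59 were higher and 2 lower, among them 44 genes higher and 1 lower, and 1785 probes had an unadjusted p under 0.05. With the replicate block 468 were called (384 higher, 84 lower), all 61 included. The block added CD40 (1.98, adjusted p from 0.443 to 6.55e-05), TNFAIP3 (2.42, from 0.109 to 0.000314), IRF4 (3.05, from 0.0965 to 0.00204), FCER2 (1.33, from 0.325 to 0.000623) and SOCS1 (1.25, from 0.752 to 0.00124). The IRF4 change stands against a floor on 2 of 3 control arrays. After quantile normalization 161 probes were called, 138 higher and 23 lower, so that 85.7% were higher against 96.7%; without centring 136 were called, and in the fit on the compared groups only 33.

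Counts without 1 array were 37 and 33 without control replicate 1 and 3, and 40, 106 and 39 without replicate 1, 2 and 3 of the combination. TNFAIP3 passed the threshold without replicate 2 of the combination (adjusted p = 0.0176), after quantile normalization (0.0357) and without centring (0.0286). CD80 and IER5 lost the call when any array of these groups but replicate 2 of the combination was left out (0.0859 to 0.182), as did LMO2 (0.0808 to 0.246). CD83 lost it without control replicate 2 or 3 or combination replicate 1 or 3 (0.127 to 0.178), LTA and DDX11-AS1 without control replicate 1 or 3 or combination replicate 1 or 3 (0.0583 to 0.127), and GBP1 without control replicate 1 or 2 or combination replicate 1 or 3 (0.0525 to 0.0663). IL2RA lost it without control replicate 1 (0.0989) or 3 (0.101), and DUSP5 without control replicate 3 (0.0543). Without a filter CD80, CD83, IER5, LMO2 and LTA lost it (0.0632 to 0.103), and LMO2 also without a floor (0.0514). In the fit on the compared groups only CD80, IER5, IL2RA, LMO2, LTA and DDX11-AS1 lost it (0.0757 to 0.221). Without replicate 2 of every group LTA, BCL2A1, DUSP5, IL2RA, CD83, DDX11-AS1 and LMO2 lost it (0.0759 to 0.122), while TNFAIP3 (0.0319) and SOCS1 (0.0249) passed. Other probes of FAS and CFLAR gave no call, with an adjusted p of 0.0825 for FAS, and another CFLAR probe gave a log2 change of -0.013.

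The gene groups of the combination were led again by NF-kB target genes, of which 9 of 28 were called higher and 18 over the list alone, with a median of 1.12 (camera adjusted p = 3.23e-42, adjusted p = 0.122 with an estimated correlation). BCL2A1, CCL3, CD83, CFLAR, TRAF1, NFKBIA, NFKBIZ (2.11 ± 0.23), the chemokine CCL5 (1.88 ± 0.27) and LTA were the called members. Costimulation and activation surface molecules held 5 called rises in 20, those of FAS, CD83, IL2RA, CD80 and CD58, and 10 over the list alone, FCER2 and the activation marker CD69 (1.29 ± 0.24) included (camera adjusted p = 1.39e-20, adjusted p = 0.122 with an estimated correlation). Chemokines and receptors held 5 in 14 and 6 over the list alone (camera adjusted p = 6.34e-11, adjusted p = 0.290 with an estimated correlation). Interferon-stimulated genes held 1 called rise in 20, that of GBP1, 9 over the list alone and 11 with the block, with a median of 0.93 (camera adjusted p = 3.02e-15, adjusted p = 0.445 with an estimated correlation).

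IL-4 and STAT6 target genes passed as well, with CCL17 called among 16, 4 higher over the list alone (CCL17, IRF4, FCER2 and the AP-1 factor BATF with 1.47 ± 0.29) and 5 with the block (camera adjusted p = 2.66e-05, adjusted p = 0.579 with an estimated correlation). Survival genes (2 of 10 called, 2 over the list alone) gave a camera adjusted p = 2.05e-07, and MAPK and receptor feedback (1 of 15, DUSP5, and 4 over the list alone) 1.74e-06, with adjusted p = 0.445 with an estimated correlation for both. MHC class I presentation held 0 calls by limma in 15, 1 over the list alone (HLA-F, 1.13 ± 0.30) and 4 with the block, the peptide transporter gene TAP1 among them (1.47). CD40 signalling components held 0 in 16, 2 over the list alone (CD40 and TANK) and 3 with the block. Their camera adjusted p was 0.00458 and 0.0210, with adjusted p = 0.999 with an estimated correlation for both. Germinal centre B cell genes were shifted down with a median of -0.38, although LMO2, their 1 called member of 17, rose; over the list alone LMO2 was called higher and RGS13 (-0.85 ± 0.22) lower (camera adjusted p = 0.00753, adjusted p = 0.999 with an estimated correlation). Immediate early genes (1 of 19 called, 2 over the list alone) gave 0.0335, with adjusted p = 0.939 with an estimated correlation. The block added JAK-STAT and SOCS components (0.00827), cholesterol synthesis (0.00244) and a downward shift of cytoplasmic ribosomal proteins (0.0325), and quantile normalization added MHC class II presentation (0.0270).

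What IL-4 added to anti-CD40 was tested by setting the combination against anti-CD40 alone. CCL17 rose a further 7.50-fold (95% interval 4.97 to 11.3, n = 3 arrays per group, limma adjusted p = 0.00568) and DOCK10 3.32-fold (2.54 to 4.35, 0.00744), with the 3 arrays of the combination above the 3 anti-CD40 arrays in both. These were the 2 called probes, and 843 had an unadjusted p under 0.05. With the block 6 were called, among them, chosen after their values were seen, MKNK1 (1.23) and TEX14 (1.15). CCL17 lost the call without anti-CD40 replicate 3 (adjusted p = 0.0698) and in the fit on the compared groups only (0.0969). DOCK10 lost it without anti-CD40 replicate 1 (0.0814) or 3 (0.0845) or combination replicate 1 (0.0825), after quantile normalization (0.241), without centring (0.0971) and in the fit on the compared groups only (0.268), and its other probe gave 0.34. Without replicate 2 of every group both lost it (0.811 each). The count was 1 without anti-CD40 replicate 1 or combination replicate 1. It was 0 by limma without anti-CD40 replicate 3, with 835 probes at an unadjusted p under 0.05.

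Camera with the preset correlation placed IL-4 and STAT6 target genes and NF-kB target genes higher with the combination than with anti-CD40 alone (adjusted p = 0.00392 and 0.00574), with 1 of 16 and 0 of 28 members called by limma and 1 each over the list alone. Their medians were 0.05 and 0.03, and both gave adjusted p = 0.989 with an estimated correlation and 0.994 by fry. Chemokines and receptors (1 of 14 called, 2 over the list alone) gave 0.0241 and survival genes (0 of 10 called, 1 over the list alone) 0.0418. These 2 lists had adjusted p = 0.989 with an estimated correlation as well, and the 4 medians lay between 0.03 and 0.20. CCL17 was the 1 called member of both IL-4 and STAT6 target genes and chemokines and receptors. The block added MHC class I presentation (0.0358).

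What anti-CD40 added to IL-4 followed from the combination against IL-4 alone. CCL17 rose 36.8-fold, CXCL10 29.5-fold, EBI3 26.6-fold, KIF26B 21.4-fold, FAS 14.6-fold, BCL2A1 10.4-fold, TRAF1 8.79-fold, NFKBIA 6.51-fold and CCL3 6.29-fold, and DDX11-AS1 fell by 1.28 on the log2 scale (SE 0.19). The limma adjusted p was 5.6e-06 for CCL17 and EBI3, 7.69e-06 for CXCL10 and KIF26B, 0.00014 for FAS and 0.0298 for DDX11-AS1. In all 32 probes were called, 31 higher and 1 lower, with 945 at an unadjusted p under 0.05, and 209 with the block (173 higher, 36 lower). The count was 87 after quantile normalization, 81 without centring and 17 in the fit on the compared groups only. DDX11-AS1 lost the call when any IL-4 array or combination replicate 1 or 3 was left out (0.120 to 0.198), after quantile normalization (0.0750), without centring (0.0898) and without a filter (0.107). Without replicate 2 of every group BCL2A1 (0.175) and DDX11-AS1 (0.253) lost it. In the fit on the compared groups only DDX11-AS1 (0.187) and CCL3 (0.0726) lost it, and the other FAS probe was not called (0.386).

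Of 13 lists past the threshold in this comparison, NF-kB target genes (5 of 28 called, 17 over the list alone, median 0.96), costimulation and activation surface molecules (2 of 20, 9 over the list alone) and chemokines and receptors (4 of 14, 6 over the list alone) had camera adjusted p = 1.33e-57, 7.21e-27 and 9.08e-20, and adjusted p = 0.0583, 0.0583 and 0.0661 with an estimated correlation. Interferon-stimulated genes held 0 calls by limma in 20 and 4 over the list alone (6.69e-20, and adjusted p = 0.221 with an estimated correlation). The medians of cytokines, plasma cell differentiation and immediate early genes lay just below 0 (-0.05, -0.04 and -0.02) while their means (0.41, 0.21 and 0.18) and the test were upward, with 1, 0 and 0 members called by limma and 2 each over the list alone. The other 9 lists had camera adjusted p between 9.17e-11, for survival genes, and 0.00818, and adjusted p = 0.221 to 0.706 with an estimated correlation. Germinal centre B cell genes were the 1 list shifted down (median -0.40). The block added CD40 signalling components (0.0227), cholesterol synthesis (0.00443) and a downward shift of G1 to S phase genes (0.0176).

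The single stimuli were also set against each other. CXCL10 was higher with anti-CD40 than with IL-4 by 4.64 ± 0.30 on the log2 scale. EBI3, KIF26B, FAS, TRAF1 and CXCL11 were 30.6-fold, 22.8-fold, 13.8-fold, 8.25-fold and 7.71-fold higher, and NFKBIA, CCL17 and CD80 6.27-fold, 4.90-fold and 3.48-fold. Higher with IL-4 were DOCK10, with a log2 difference of -1.76 ± 0.18 (limma adjusted p = 0.000964), the T cell receptor zeta chain gene CD247 (-1.66 ± 0.27), the histone demethylase gene KDM7A (-1.60 ± 0.20), the transcription factor gene NFIX (-1.49 ± 0.23), PGM5 (-1.45 ± 0.22) and DDX11-AS1 (-1.16 ± 0.19). The 49 called probes comprised 37 higher and 12 lower with anti-CD40, 1322 had an unadjusted p under 0.05, and 318 were called with the block (187 higher, 131 lower).

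The count of this comparison was 28 and 27 without anti-CD40 replicate 1 and 2, 25 and 24 without IL-4 replicate 1 and 3, 117 after quantile normalization, 101 without centring, 31 without a filter and 24 in the fit on the compared groups only. CD80 lost the call when any array of these groups but anti-CD40 replicate 2 was left out (0.0565 to 0.0829), CD247 without anti-CD40 replicate 1 or 2 or IL-4 replicate 1 or 3 (0.152 to 0.203), PGM5 when any array but IL-4 replicate 2 was left out (0.0874 to 0.142), and NFIX and DDX11-AS1 whichever of the 6 was left out (0.0574 to 0.249). Without a filter CD247, NFIX, PGM5 and DDX11-AS1 lost it (0.0755 to 0.143), and in the fit on the compared groups only these, KDM7A and CD80 (0.0554 to 0.292). Quantile normalization (0.0982) and no centring (0.125) ended the call of DDX11-AS1, and trend and robust moderation that of NFIX (0.0552). Without replicate 2 of every group PGM5, KDM7A, CD247, NFIX, CCL17 and DDX11-AS1 lost it (0.0896 to 0.260). The other DOCK10 probe gave 0.18, and the other FAS probe was not called (0.0942). Of 10 lists past the threshold, NF-kB target genes (4 of 28 called, 14 over the list alone), costimulation and activation surface molecules (3 of 20, 6 over the list alone) and chemokines and receptors (3 of 14, 5 over the list alone) had camera adjusted p = 4.87e-39, 4.21e-17 and 8.65e-16, and each adjusted p = 0.131 with an estimated correlation. The other 7 lists had camera adjusted p between 1.9e-13, for interferon-stimulated genes, and 0.00357, for germinal centre B cell genes (median -0.31), and adjusted p = 0.470 to 0.962 with an estimated correlation. The block added MHC class I presentation (0.00649), cholesterol synthesis (0.0153) and a downward shift of G2 to M phase genes (0.0101).

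The interaction asked whether the combination departed from the sum of the single log2 changes. CXCL10, EBI3 and FAS, with changes in the combination close to those of anti-CD40 alone, had no detectable departure, and neither had any other probe after adjustment over all probes: limma called 0, with a lowest adjusted p of 1.00, and 371 had an unadjusted p under 0.05. With the block limma called 0, with a lowest adjusted p of 0.503 and 1377 at an unadjusted p under 0.05. No gene list passed, 0 of 33 by camera or fry. The median over all probes was -0.12, against -0.01 without centring.

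The transcripts changed by anti-CD40 overlapped those changed by the combination. Of the called probes, 42 were shared, 41 higher and 1 lower, against 0.0815 and 0.000113 expected of independent lists, and 0 in simulated unchanged groups that share the controls. With the block 247 were shared, 235 higher and 12 lower. Over all tested probes, which are not independent, the log2 changes correlated at 0.667 (0.501 simulated), and their covariance was 0.0622, against 0.0506 simulated with independent arrays and 0.0249 when the replicate deviations were kept, a simulation added after the other was seen. Anti-CD40 and IL-4 shared 0 called probes by limma. Their covariance of 0.0294 lay below the value simulated with independent arrays. It lay above all 20 draws that kept the replicate deviations (0.0238 to 0.0260), so its side depends on the pairing, which was taken from the data. Their correlation was 0.419, below the 0.501 of both simulations, so no excess is read from these values. With the block anti-CD40 and IL-4 shared 3 called probes, namely MAP3K8 (1.45 and 1.27), LMO2 (1.72 and 1.09) and a probe of several symbols that went opposite ways (-0.92 and 1.48). The 3 control arrays cannot be split into sets of at least 2, so for anti-CD40 and IL-4 part of any excess may come from the shared controls. For anti-CD40 and the combination, a check not planned beforehand compared anti-CD40 against control with the combination against IL-4, which share no array. These changes correlated at 0.425 over all tested probes. Of the 100 probes with the lowest p in either comparison, 99% moved the same way in the other, an agreement that shared controls cannot give.

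Markers of other cell types were tested for a shift with the stimuli, and no such list passed the threshold. Markers of T and NK cells, of monocytes and myeloid cells and of fibroblasts and epithelium gave camera adjusted p = 0.573, 0.580 and 0.838 for anti-CD40 against control, and 0.918, 0.994 and 0.918 for the combination. Limma called 0 of their 9, 6 and 7 measured members. Housekeeping genes gave 0.838 and 0.994. Their median and mean lay above 0 in both comparisons (0.08 and 0.06, then 0.06 and 0.09) while camera, which sets a list against the other genes, placed them lower. The medians of the T and NK cell markers were -0.06 and -0.02, and their mean in the combination was 0.03. Myeloid markers had a median of 0.11 in the combination and were placed lower, and markers of fibroblasts and epithelium had a median of 0.08 with anti-CD40 and were placed lower.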

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

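The adjustment over the sentinel genes, the tests that subtract background and the draws for the interaction were chosen only after the result was seen. CCL17, the CCR4 ligand, stood out because its response to IL-4 differed with and without anti-CD40. Its interaction was 1.74 ± 0.39 on the log2 scale, with a limma adjusted p of 0.0154 over the 22 sentinel genes and 1.00 over all probes (with the replicate block 0.000435 and 0.503). Its mean scaled intensity was 0.158 in control, 0.359 with IL-4, 1.73 with anti-CD40 and 13.6 with both, and the other 21 sentinel genes had an adjusted p of at least 0.957 (with the block at least 0.0806, for CD40 with an interaction of -0.69).

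One array as the source is argued against, since the lowest interaction over the 12 fits without 1 array was 1.43 (SE 0.32, without replicate 1 of the combination) and the highest 1.93. Background left in the dim control arrays stays open. Subtracting each array's 10th percentile left 1.57 ± 0.42 and its 30th percentile 1.26 ± 0.49, while its 40th percentile left 0.87 ± 0.57 and its median -1.12 ± 1.82, with the control too close to the subtracted level for a verdict. A joint action of CD40 and IL-4 signalling on CCL17 may underlie the interaction, as a hypothesis that no test here separates from such background. Nor can a joint action be told apart from a different culture time of the control, which the titles do not give.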

How the results depend on the processing

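The fits with 2 choices together and those without replicate 2 of every group were chosen only after the data were seen. Of 65 calls of named genes, 33 held in every alternative and 32 ended in at least 1, leaving other probes of the gene aside. Other probes did not give 8 of the 65 calls, those of CFLAR, FAS and DOCK10, and 28 held in every alternative and by every other probe. Each fit without 1 array or without replicate 2 was counted separately, so the same call can count several times. Over named genes, such fits ended a call 132 times and began a call 3 times. The fit on the compared groups only ended 20 calls, no filter 15, no centring 5 and quantile normalization 4, and the replicate block began 7. No centring and quantile normalization began 1 each. The block began 12 with quantile normalization and 10 without centring. Those with quantile normalization included BCL6 lower with anti-CD40 (limma adjusted p = 0.0163) and the combination (0.0117) and IL4R lower with the combination (0.0239). FCER2 (0.0397) and SOCS1 (0.0296) were among them as rises with anti-CD40. The changes of direction came from other probes: CFLAR gave -0.36 in anti-CD40 against control and -0.013 in the combination, and DOCK10 gave -0.24 in IL-4 against control and 0.18 in anti-CD40 against IL-4. What those probes detect was not tested. Limma called 0 probes for the interaction in every alternative, with 29 to 1726 at an unadjusted p under 0.05. The floor, the stricter filter, the 2-fold requirement and 1 probe per gene moved no count by over 1.5 times.

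Counts are given in the order anti-CD40, IL-4 and the combination against control, the combination against anti-CD40 and against IL-4, and anti-CD40 against IL-4. Without alternatives they were 51, 1, 61, 2, 32 and 49. Quantile normalization gave 113, 2, 161, 1, 87 and 117 probes, and no centring gave 86, 0, 136, 1, 81 and 101, and the cause was not tested. The replicate block gave 316, 12, 468, 6, 209 and 318, and it ended the call of no named gene. The block with quantile normalization gave 491, 13, 816, 7, 398 and 547, and the block without centring 392, 6, 643, 6, 389 and 464. The fit on the compared groups only, with fewer arrays behind the spread, gave 34, 0, 33, 0, 17 and 24, and was not run for the interaction. No filter gave 33, 2, 45, 2, 27 and 31 with more probes to adjust over, and trend and robust moderation gave 2 for IL-4. Beside the counts of 0, limma had 814 probes at an unadjusted p under 0.05 for IL-4 without centring, and 840 and 688 for the 0 counts in the fit on the compared groups only.

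Leaving out 1 array, in fits without the block, gave 23 to 35, 0 to 3, 33 to 106, 0 to 2, 22 to 48 and 24 to 38 probes. Without replicate 2 of every group, whose arrays had the highest medians, the counts were 35, 0, 64, 0, 28 and 25, with 1841 and 1595 probes at an unadjusted p under 0.05 beside the counts of 0. With an estimated correlation and no block 0 gene lists passed in any comparison, and by fry without the block 3, 0, 3, 0, 3 and 0. An estimated correlation with the block was not run. With the block and the preset correlation 3 lists passed for IL-4. The single stimuli shared 3 called probes with the block. Signal over background limits the folds of dim probes, and the 3 arrays per group limit the precision of all of them.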

Other observations

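The test on separate arrays, the tests of scaling and of the replicate sets for IL-4, and the draws for the interaction were chosen only after the result was seen. Several further genes changed with anti-CD40 and with the combination, named here after their values were seen. SEMA7A, a membrane-anchored semaphorin, rose by 2.72 ± 0.33 with anti-CD40 and 2.73 ± 0.33 with the combination on the log2 scale. The kinase gene SGK1 rose by 2.15 ± 0.20 and 2.91 ± 0.20, the butyrophilin gene BTN2A2 by 2.44 ± 0.29 and 2.33 ± 0.29, and MAP3K8, a kinase upstream of ERK, by 1.45 ± 0.19 and 1.95 ± 0.19. The transcription factor gene RUNX3 rose by 1.70 and 1.68, and NFKBID, which encodes a nuclear inhibitor of NF-kB, by 1.57 and 1.58. GPR183, an oxysterol receptor that guides B cells, rose by 2.67 ± 0.35 with the combination, and the syndecan gene SDC4 by 1.99 ± 0.28.

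With the replicate block, APOL3 rose by 2.87 and 2.95 and CXCL9, another ligand of CXCR3, by 2.32 and 2.45, and CCDC85A fell by 1.26 and 1.39. None of these genes was called without the block. The limma adjusted p was then 0.196 and 0.124 for APOL3, 0.198 and 0.115 for CXCL9, and 0.231 and 0.113 for CCDC85A. Probe 141025, which has no symbol, rose by 4.09 ± 0.21 and 4.24 ± 0.21.

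Other splits of the arrays were compared with the real one. In each of the 6 pairwise comparisons 1 of 10 splits, the real one, called as many probes, and 10 splits are too few for a share under 0.05. The real counts were 51, 1, 61, 2, 32 and 49 for anti-CD40, IL-4 and the combination against control, the combination against anti-CD40 and against IL-4, and anti-CD40 against IL-4. The highest other counts were 1, 0, 2, 0, 0 and 0, and 0 in each among the splits that part all same-number pairs (4 with the real one), the other 6 splits keeping a pair together. For the interaction 100 of 100 draws called at least the real 0 probes of limma (371 at an unadjusted p under 0.05), the highest calling 3, an outcome that a real count of 0 fixes, so these draws decide nothing.

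Few probes passed the threshold for IL-4 alone. Array scaling as the source is argued against, since quantile normalization and no centring gave at most 2 probes. Differences between the replicate sets may hide part of the response, consistent with the 12 probes called with the replicate block. A response too small for 3 arrays per group stays open. Of the 100 probes with the lowest p, 77% moved the same way in the combination against anti-CD40, on other arrays. The highest other split of those arrays also reached 77%. For the other splits, though, the larger of the shares moving the same and the opposite way was taken. Each of them also mixes both groups unevenly, so part of the real difference remains in it. In the reverse direction the real share was 90%, which was not set against other splits. The bound set against this explanation was met by the tie at 77%. The tie shows the real share neither above nor below what regrouped arrays can give, and this reading was chosen after the value was seen.

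Camera with the preset correlation placed interferon-stimulated genes higher with anti-CD40, with 1 of 20 called, adjusted p = 0.565 with an estimated correlation and 0.314 by fry. Variation of the gene group between cultures stays open, although the mean of the list was higher in 6 of 6 same-number pairs with and without anti-CD40, with a lowest difference of 0.69, and the 6 pairs with and without IL-4 differed by -0.16 to 0.33. The bound set against this explanation was passed, but it took the 6 pairs as separate cultures, which no label states: with 1 culture per group they hold 2 separate differences, too few to measure such variation, and this reading was chosen after the value was seen. A shift of all probes of like brightness is argued against, since 0% of 10000 matched random lists had a median as high as 0.87, the highest being 0.24. A response of these genes to CD40 ligation may underlie the shift, as a hypothesis found on the same data that the lowest difference of 0.69 separates from such variation only if the arrays of a group came from separate cultures.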
